A study of Arabidopsis thaliana with 4 samples.

How the data were processed

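Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on Arabidopsis thaliana inflorescences. The AGAMOUS protein (AG) was tagged with green fluorescent protein and recovered with an anti-GFP antibody. The plants carried a dexamethasone-inducible AP1-GR transgene in an ap1 cal background, in which an application of dexamethasone starts flower formation in many meristems together, and tissue was taken 4 days later. The design has 2 groups, AG-GFP plants and plants without the tagged protein as the negative control, with 2 libraries in each. Per the labels, each negative control library served the AG-GFP library of the same replicate number, and the first control library was also used in another series.

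The deposited data are a peak list and a target gene table for the whole series. The genome build was TAIR10, per the submitters' processing notes. The aligner, the peak caller, its threshold and the treatment of the replicates are not given in the sources used here. Neither table holds a value per library, so no spread between replicates can be given, the sequencing depth is unknown, and no interval that needs read counts is given.

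In the peak list, each of the 1421 peaks has a start, an end, a width, a peak position and a Poisson score, per the file headers, as made by the authors. The headers of the position and score columns were exchanged in the deposited peak list. The values under the score header lie within the start and end of their peak for all 1421 peaks. The values under the position header recur in the target table, where all 4081 entries above 0, the maxima per gene included, are also found in the peak list. The columns were therefore read by their values. The target table deposited by the authors gives, for 1958 genes, the highest peak score from 3000 bp upstream of the 5' end to 1000 bp downstream of the 3' end, per the file headers. It also gives the highest score in each of 5 regions of that stretch. A score was used only to describe, rank or filter peaks within the list.

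Gene names, gene classes and neighbourhood came from a RefSeq gene table of the TAIR10.1 assembly, which names 27444 protein-coding nuclear genes. Of the 1958 target genes, 1916 (97.9%) matched it by locus identifier, and all 192 genes of the fixed lists did. The gene spans of that table were used for neighbourhood, length and the share of peaks inside genes, and none of its coordinates is printed. As a check, the 3 upstream scores of the target table were recomputed from the peak positions and these spans. They were recovered within 0.006 score units, on 1 of the 2 possible strands, for 1697 of 1916 genes (88.6%). The gene table holds no strand, exon or UTR, and no genome sequence was used here. The planned CArG-box tests, the split of peaks by exon, intron and UTR, and the alternative asking for a minimum share of each peak were therefore not run.

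A set of 12 gene lists with 192 genes was fixed from textbook knowledge in advance. Each list was compared with all other protein-coding genes for presence in the target table by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 12 lists and a threshold of 0.05. Transcription factor families with at least 5 members named by a symbol prefix and a number were tested in the same way. Shares carry 95% exact Clopper-Pearson intervals, which treat the genes as independent and cover counting error only. For a list with a count of 0, the upper limit is that of 3 genes out of the list's members. Peak positions inside protein-coding gene spans were compared with 10000 circular shifts of the peak list along each chromosome. Tests were run in Python 3.11.15 with scipy 1.17.1, numpy 2.4.6 and pandas 2.3.3.

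By a rule set before the data were examined, the text was to name AG and the members of the fixed lists in the target table (all but 1 are named), and the members of the 4 floral lists that are not in it. It also names up to 3 members of a list with no target and the 10 peaks with the highest scores with the genes assigned to them. Genes named outside this rule are said to have been chosen after their values were seen. The alternatives set in advance were peaks at or above the median score, any overlap of the whole peak in place of its position, other assignments of peaks to genes, and 10000 random lists matched on 10 classes of gene length plus flanking intergenic space. The exact locus of a peak beside a gene was taken from the peak with the gene's score within 3000 bp of its span. The comparison of scores between lists, a repeat without the broadest peaks, and families named by synonyms were added after the data had been seen.

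The list test and the matched lists were tested on simulated data. In 100 simulated random target sets over 27444 genes, Fisher's test called 0.167% of the lists and the matched lists 0.0833%. With 12 members of the leaf list planted as targets, both called that list in 100% of the sets. That is the count observed for this list, and detection of smaller counts or in shorter lists was not tested. With targets drawn in proportion to gene space, Fisher's test called 1.83% of the lists and the matched lists 0.0833%.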

Results

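The binding of AG, the MADS-domain protein that specifies stamens and carpels, was mapped in young flowers by ChIP-seq. The question was which genomic regions the tagged protein occupies at an early to intermediate floral stage, 4 days after induction, against plants without the tag. Each group had 2 libraries. All scores and peak positions below come from the authors' deposited tables, which give 1 score per peak and no value per library. They carry no replicate error, and a rank of scores describes this peak list only.

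Of the 5 highest-scoring AG-GFP peaks, 4 were assigned to floral organ identity genes, 2 of them together with a neighbouring gene. The peak with the highest score, 12585.03, lay inside AG (AT4G18960), on chromosome 4 from 10382388 to 10388112 (TAIR10). The next was upstream of AP3 (AT3G54340), the petal and stamen identity gene, with a score of 5695.79 on chromosome 3 from 20120922 to 20121669. It also lay within 1000 bp downstream of EMB1967 (AT3G54350). Next in score was the peak 2000 to 3000 bp upstream of SEP3 (AT1G24260), a MADS-box cofactor gene for the floral organ identity proteins, with 5153.51 on chromosome 1 from 8598539 to 8599080. That peak was nearer to AT1G24265, of which it lay 1000 to 2000 bp upstream. The fifth, with 3529.42, lay inside AP1 (AT1G69120), a sepal and petal identity gene and the source of the inducible transgene, on chromosome 1 from 25982690 to 25987190.

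The other 6 of the 10 highest-scoring peaks lay at other genes. A score of 4142.8 was given to a peak inside AT3G14220, annotated as a GDSL lipase, and 3446.61 to a peak within 1000 bp upstream of AT5G21280, annotated as a hydroxyproline-rich glycoprotein. The peak assigned to GRF5 (AT3G13960), a growth-regulating transcription factor gene, scored 2992.89 and lay 2000 to 3000 bp upstream. It is shared with AT3G13950, which it follows within 1000 bp. The peak at 2927.42 is assigned to AT1G28040, AT1G28060 and BBX13 (AT1G28050), a B-box zinc finger gene, and lies within 1000 bp upstream of the last. Upstream peaks of XTH27 (EXGT-A3, AT2G01850), a xyloglucan-modifying enzyme gene, and TOE3 (AT5G67180), an AP2-domain gene, scored 2673.32 and 2589.52.

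The list as a whole held 1421 peaks that covered 401950 bp. The median width was 234 bp (quartiles 154 and 339 bp) and the median score 139.67 (quartiles 76.82 and 278.78, range 36.35 to 12585.03). Width and score rose together across peaks (Spearman's rho 0.71), which are not independent replicates. The peaks at AG and AP1 were 5725 and 4501 bp wide, against a median of 542 bp for the 9 highest-scoring peaks other than AG. A run of 14 peaks with gaps of at most 2000 bp lay on chromosome 1 from 9567556 to 9592023. The number per chromosome ran from 10.7 to 12.7 per Mb and a departure from the number expected by length was not detected (chi-square test, p = 0.166).

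**Figure D1:**
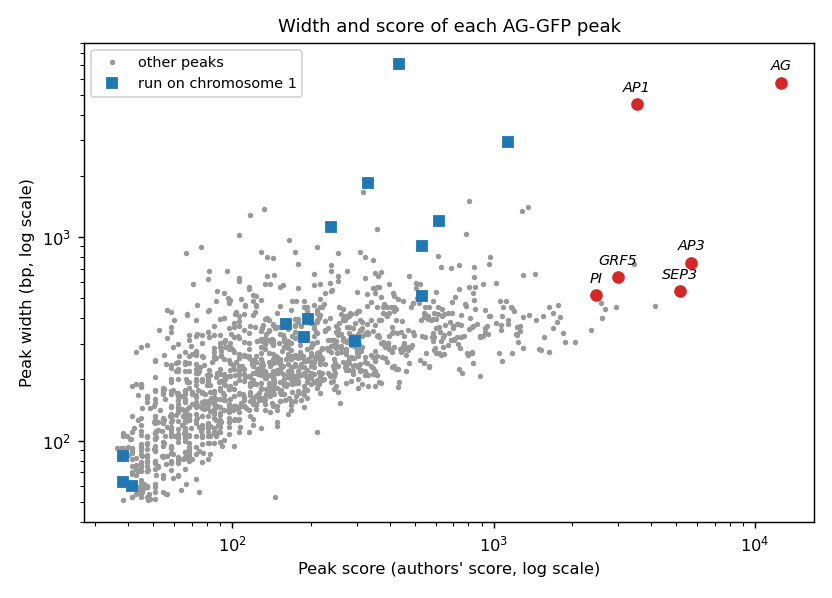
Width of each of the 1421 peaks in bp against its score, both on log axes, with the highest peak of 6 named genes in red and the 14 peaks of a run on chromosome 1 in blue. The peaks at AG (5725 bp) and AP1 (4501 bp) are far wider than those at AP3 (748 bp) and SEP3 (542 bp).

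**Figure D2:**
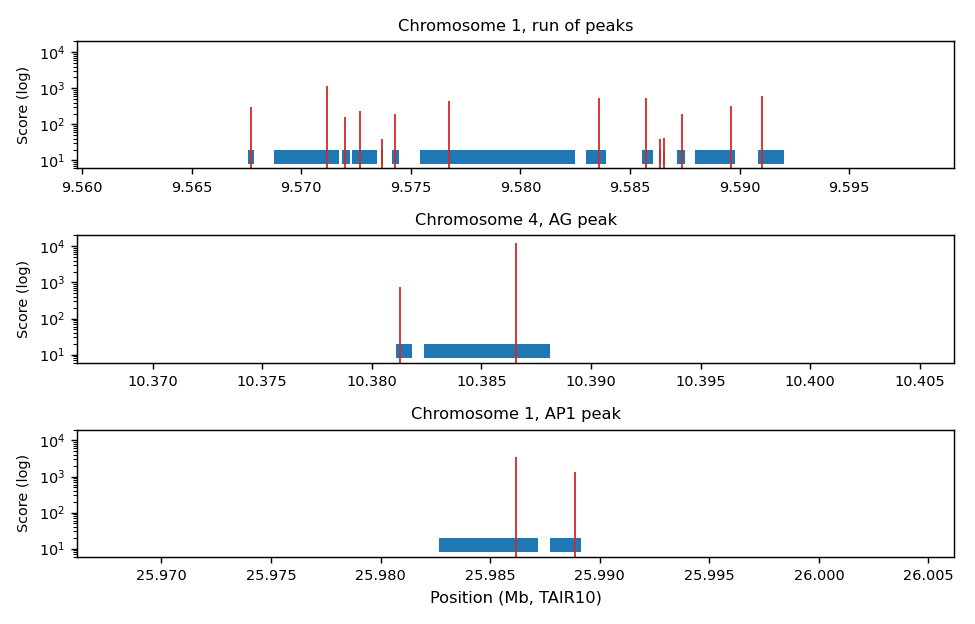
Peaks in 40000 bp windows around the run of 14 peaks on chromosome 1, the AG peak and the AP1 peak, with position in Mb on the x axis. Red lines stand at each peak position and reach its score on a log axis, and blue bars show each peak's extent at an arbitrary height. The run spans 24468 bp.

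Peaks lay inside genes less often than shifted peaks did, and more target genes had a peak within 1000 bp upstream than in any other region of the table. Of the 1421 peak positions, 449 (31.6%) fell inside protein-coding gene spans, against a mean of 54.3% for shifted peak lists (95% of shifts between 48.6 and 59.8%). The difference exceeded that of every shift (permutation test by circular shifts, two-sided p = 0.0002, the smallest that 10000 shifts can give). In the authors' deposited table of 1958 target genes, 689 (35.2%) had a peak within 1000 bp upstream. A peak 1000 to 2000 bp upstream was listed for 378 genes and one 2000 to 3000 bp upstream for 379. Inside the gene, 299 genes (15.3%) had a peak, and 378 had one within 1000 bp downstream. The 299 genes follow the authors' regions and the 449 peak positions the RefSeq gene spans. These counts were not reconciled, since only the upstream regions were recomputed. Among genes with a peak in either of the nearest upstream bins but not both, 658 had it within 1000 bp and 347 at 1000 to 2000 bp (exact binomial test, two-sided p = 6.32e-23). This test treats genes as independent, although genes can share a peak. Its null is equal counts in both bins. No shifted baseline was run for the bins, so the spacing of genes was not accounted for. Peaks linked to target genes numbered 1237, of which 577 had 1 gene, 497 had 2 and 163 had 3 or more. The gene that a shared peak acts on cannot be read from position. Of 1915 linked target genes, 1426 had a peak that was also linked to another target gene. Among the list members named below, this applies for example to FLC, SVP, SHP2, SEP2, HEC1, VDD, EMS1, TPD1, TGA9, SERK1, SERK2, RGL2 and SCR.

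Among the floral organ identity genes, 9 of 13 (69.2%, 95% exact interval 38.6 to 90.9%) were targets, against 6.59% of other protein-coding genes. The odds ratio was 31.9 (95% interval 8.89 to 142, Fisher's exact test, adjusted p = 8.06e-08). Beside AG, AP3, SEP3 and AP1, these were PI, AP2, SEP2, SHP1 and SHP2. PI (AT5G20240), the partner of AP3, had a peak of 2459.62 within 1000 bp upstream, on chromosome 5 from 6828744 to 6829262. SHP2 (AT2G42830), a carpel and fruit MADS-box gene closely related to AG, had one of 1495.24 on chromosome 2 from 17819765 to 17820047. Its paralog SHP1 (AT3G58780) had a peak inside the gene of 65.95. AP2 (AT4G36920), which encodes an AP2-domain protein that opposes AG, had a peak of 859.87 at 1000 to 2000 bp and one of 541.79 further upstream. SEP2 (AT3G02310) had one of 740.69 within 1000 bp upstream. SEP1, SEP4, CAL and STK were not in the table.

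Of the genes for floral meristems and flowering, 13 of 24 (54.2%, interval 32.8 to 74.4%) were targets, with an odds ratio of 16.8 (95% interval 6.92 to 41.4, Fisher's exact test, adjusted p = 6.76e-09). The highest scores in this list were at the flowering repressor FLC (1223.64), the MADS-box gene SVP (1077.97), and SOC1 (908.49) and FD (781.31), both of which promote flowering. FLC, SVP and FD had their highest peak 2000 to 3000 bp upstream, and SOC1 within 1000 bp upstream. SUP, which sets the boundary between stamens and carpels, scored 365.01, UFO 373.97 and FUL 241.9. CLV1 (109.48), PNF (105.6), STM (97.13), ULT1 (81.04) and LFY (58.19) all scored below the median peak. WUS, which maintains the meristem, and KNU, which acts with AG in ending meristem activity, were not in the table. Neither were CLV3, PAN, TFL1, FT, KNAT1, RBE, SEU, LUG and PNY.

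Genes for stamens and for carpels were both enriched. With peaks limited to 1000 bp upstream and the gene, 4 genes of each list were left, and both still passed (adjusted p = 0.0062, Fisher's exact test). Of the stamen and anther genes, 9 of 19 (47.4%, interval 24.4 to 71.1%) were targets (odds ratio 12.7, 95% interval 4.58 to 35.0, Fisher's exact test, adjusted p = 3.61e-06). TGA10 had a peak of 965.18 inside the gene on chromosome 5 from 2123523 to 2124323, and its relative TGA9 one of 376.22 downstream. The glutaredoxin gene ROXY1 scored 630.5, and the receptor gene EMS1 and the gene of its ligand TPD1 scored 403.5 and 266.42. SPL (NZZ, AT4G27330), which starts sporogenesis, had a peak of 162.95 at 2000 to 3000 bp upstream, on chromosome 4 from 13685934 to 13686243. SERK2 scored 179.13, SERK1 143.81, and DAD1, a jasmonate synthesis gene active in stamens, 47.19 downstream of the gene. MYB21, MYB24, MYB26, AMS, TDF1, MS1, DYT1, BAM1, BAM2 and ROXY2 were not in the table.

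Of the carpel and ovule genes, 7 of 19 (36.8%, interval 16.3 to 61.6%) were targets (odds ratio 8.25, 95% interval 2.75 to 22.8, Fisher's exact test, adjusted p = 0.000273). CRC (AT1G69180), a YABBY gene of carpels and nectaries, had a peak of 1514.19 at 2000 to 3000 bp upstream, on chromosome 1 from 26011595 to 26011872. HEC1 and HEC2, bHLH genes of the transmitting tract, scored 1087.38 and 488.04. ETT, an auxin response factor gene of gynoecium patterning, scored 678.47 and VDD 351.68, while the boundary genes CUC2 and CUC1 scored 152.42 and 58.44. SPT, HEC3, STY1, STY2, the NGA1 to NGA4 genes, IND, ALC, BEL1 and INO were not in the table.

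Leaf genes were also enriched among the targets. Of the genes for leaf growth and polarity, 12 of 27 (44.4%, interval 25.5 to 64.7%) were targets (odds ratio 11.3, 95% interval 4.84 to 26.0, Fisher's exact test, adjusted p = 1.87e-07). Beside GRF5, the highest scores were at PHV (1045.14), AS1 (727.5) and GRF2 (509.13). PHB (211.27) and REV (168.86) were targets with PHV, and all 3 encode class III HD-ZIP proteins that specify the upper leaf side. JAG, a growth regulator of lateral organs, had a peak of 327.59 downstream of the gene, and the boundary genes BOP1 and BOP2 scored 301.85 and 204.08. GRF3 scored 101.69, KAN2 58.19 and TCP4 47.19. Of the trichome genes, 7 of 17 (41.2%, interval 18.4 to 67.1%) were targets (odds ratio 9.91, 95% interval 3.20 to 28.9, Fisher's exact test, adjusted p = 0.000142). GL1, the MYB gene that starts trichomes, scored 358.33. CPL3 (193.9), CPC (110.99) and TRY (54.43) encode small MYB proteins that restrain trichomes or specify root hairs. TTG2 scored 105.6, GIS 47.78 and GL3 44.86. With only the peaks at or above the median score, 2 trichome genes were left and the list no longer passed (adjusted p = 0.17, Fisher's exact test, against 0.000139 to 0.0125 in the other 4 alternatives).

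Among hormone genes, the gibberellin list passed the test and the auxin and jasmonate lists did not. Of the gibberellin genes, 5 of 16 (31.2%, interval 11.0 to 58.7%) were targets (odds ratio 6.42, 95% interval 1.75 to 20.1, Fisher's exact test, adjusted p = 0.00511). They were the receptor genes GID1C (939.57, inside the gene) and GID1B (210.92), the DELLA repressor genes RGL2 (396.63) and GAI (86.64), and the catabolic gene GA2OX1 (62.03). The other 11 genes of the list, which encode synthesis and catabolic enzymes, receptors and DELLA proteins, were not in the table. This call was lost with peaks limited to 1000 bp upstream and the gene (2 genes, adjusted p = 0.166) or to the nearest gene (3 genes, adjusted p = 0.0575, both Fisher's exact test, against 0.00504 to 0.032 in the other 3 alternatives). YUC4 (122.5) and ARF6 (168.86) were the 2 targets among 15 auxin genes (adjusted p = 0.349), and LOX3 (106.31) was the only one among 8 jasmonate genes (adjusted p = 0.506, Fisher's exact test). Their odds ratios were 2.17 and 2.02, and the 95% intervals of both included the 6.42 of the gibberellin list, so a difference between these lists was not shown.

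In the comparison lists, none of 11 photosynthesis genes, such as RBCS1A, RCA and LHCA1, and none of 10 housekeeping genes, such as ACT2, UBQ10 and UBC9, was a target. A count of 0 allows shares of up to 27.3 and 30.0% (Fisher's exact test, p = 1.0 for each list), so lists of this size could not show a share below that of all genes. Of 13 regulators of roots and seeds, SCR (396.63) and PLT1 (365.01) were targets (15.4%, adjusted p = 0.317, Fisher's exact test). The odds ratio of this list was 2.57 (interval 0.276 to 11.8). The interval included the odds ratios of the gibberellin (6.42), carpel (8.25), trichome (9.91) and leaf (11.3) lists, so a difference from these was not shown. The odds ratios of the stamen (12.7), floral meristem (16.8) and floral organ identity (31.9) lists lay above it. Their own intervals began at 4.58, 6.92 and 8.89, below the upper limit of 11.8, and so overlapped that of the root and seed list. A difference from these lists was therefore not shown either. No direct test of target shares between lists was run.

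**Figure D3:**
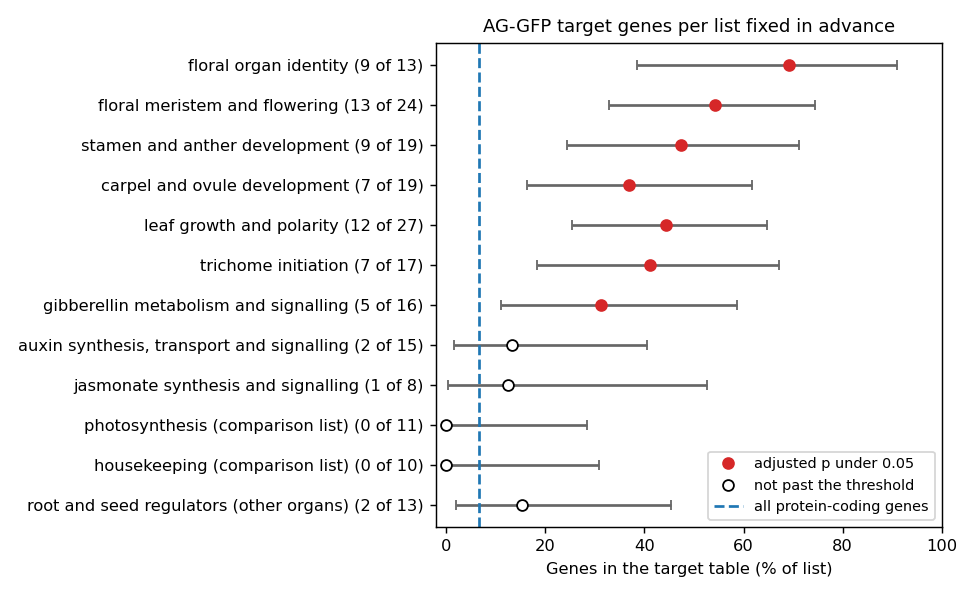
Share of each fixed gene list found in the target table, in percent, with 95% exact intervals as bars and the share of all protein-coding genes (6.62%) as a dashed line. Red points mark the 7 lists with an adjusted p under 0.05, from 31.2% for gibberellin genes to 69.2% for floral organ identity genes.

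Target genes of the floral organ identity list had the highest median score of the 7 lists. This comparison was added when the highest-scoring peaks were already known to include genes of this list, so it describes their scores and is not independent evidence. Their median score was 2459.62, against 143.81 for the other protein-coding target genes, and 8 of 9 were at or above the median peak. The mean difference was 3.48 on the log2 scale (permutation test with 100000 resamples, two-sided p = 2e-05, the smallest these resamples can give, adjusted p = 0.00014 over 7 lists). The 9 genes include AG and AP1, whose broad peaks cannot be told apart from added copies of these genes. No comparison without them is given here. For carpel and ovule genes the difference was 1.31 (permutation p = 0.0172, adjusted 0.0602), and it did not pass the threshold. The remaining 5 lists had permutation p-values of 0.0508 to 0.507 (adjusted 0.119 to 0.507). The trichome targets had a median score of 105.6 and a difference of -0.72.

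**Figure D4:**
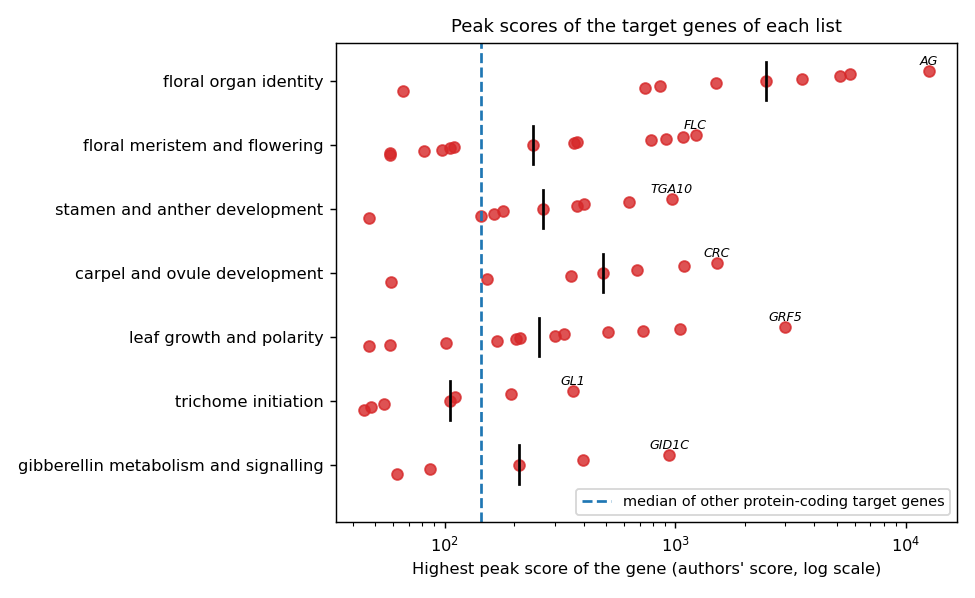
Highest peak score of each target gene, on a log axis, for the 7 lists with at least 3 targets, with the list median as a black bar and the median of other protein-coding target genes (143.81 for the floral organ identity list) as a dashed line. The floral organ identity genes lie highest, with a median of 2459.62.

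Of 13 transcription factor families named by symbol, 5 passed Fisher's exact test, and 4 of these are described here. Among homeobox genes named HB or KNAT, 9 of 44 were targets (20.5%, odds ratio 3.64, exact test, adjusted p = 0.0133), with KNAT6 (238.98) and KNAT2 (135.33) among them. Among the SPL genes of the SBP-box family, 4 of 14 were targets (28.6%, odds ratio 5.65, exact test, adjusted p = 0.0364), with SPL8 (1163.67), which acts in anther development, SPL2 (389.8), SPL11 (216.69) and SPL15 (101.69). The TCP family had 4 of 16 (odds ratio 4.71, exact test, adjusted p = 0.0477), all with scores below the median peak. The GRF prefix had 6 of 21 (28.6%, odds ratio 5.66, exact test, adjusted p = 0.0133) and mixes different kinds of protein. Of the growth-regulating factors, 5 of 9 were targets, and of the general regulatory factors (14-3-3 proteins) 1 of 11. The MYB (14 of 115, exact test, adjusted p = 0.0503), NAC, WRKY, ARF, IAA, ERF, bHLH and WOX groups did not pass. A group holds only genes whose symbol is the prefix and a number, such as 21 ERF and 13 bHLH genes. The bHLH genes HEC1 and HEC2 were thus not in the bHLH group, and these results do not cover whole families. Some of the calls per group depended on the setting. MYB genes passed with the nearest gene only (adjusted p = 0.0157) and in the alternatives added after the data were seen, without the broad peaks (0.0494) and with synonyms (0.0335), but not in the other 3 (0.0704 to 0.279, exact or permutation tests). IAA genes passed with the nearest gene only (adjusted p = 0.047, exact test, against 0.0828 to 0.736 otherwise). The SPL call was lost with the nearest gene only (2 genes, exact test, adjusted p = 0.189) and with synonyms (0.0601). No family passed against random lists matched on gene and flanking space, where 4 had an unadjusted p under 0.05 and the lowest adjusted p was 0.0529, and none passed with peaks at or above the median score. Members named here beyond the fixed lists were chosen after their values were seen.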

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

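The alternatives without the broad peaks and with families named by synonyms were chosen after the data had been seen, as was the reading of the matched lists as a test of long stretches of DNA around these genes. No paired analysis was possible because the deposited tables hold no value per library, so no replicate could be used as a block or left out. Of 60 list results under 5 alternatives, 57 stayed on their side of the threshold. The exceptions were the trichome list with peaks at or above the median score (2 genes) and the gibberellin list with peaks within 1000 bp upstream or in the gene (2 genes) or with the nearest gene only (3 genes). These sets hold fewer protein-coding target genes, 939, 908 and 1245 in place of 1817. The 60 results include the lists that did not pass in the main test. They also include the repeat without the broad peaks, where all 12 lists kept their main counts. The 57 results therefore do not measure how stable the 7 passing lists are. All 7 lists past the threshold also passed against random lists matched on gene plus flanking space. Of the transcription factor families, 5 passed in the main test, 0 with peaks at or above the median score and 0 against matched lists, and for the matched lists the cause was not tested. The TCP family had 0 targets of 16 with peaks at or above the median score, a change of direction, since its 4 peaks all score lower. Those peaks number 711 by construction. The share of peak positions inside genes was 29.8% for them, against a shifted mean of 54.3%, and 41.5% of all peaks overlapped a gene anywhere, against 58.8% (permutation p = 0.0002 for each, the smallest the shifts can give). The ratio of genes with a peak within 1000 bp upstream to those with one at 1000 to 2000 bp was 1.82 for all peaks and 1.69 for the higher-scoring ones, and 99.9% of the target genes found in the gene table were linked to a peak by position or by any overlap. Of 78 results of single families under the alternatives, 62 stayed on their side of the threshold. Without the run on chromosome 1 and the broad peaks at AG and AP1, 1405 peaks and 1952 target genes were left. Of the floral organ identity genes, 9 of 13 were still targets, since AG and AP1 each have a further peak within 2000 bp of the broad one. An artefact at these loci could give rise to the further peaks as well, so the unchanged count does not test for one. The CArG-box alternatives and the minimum share of each peak were not run, for want of sequence and strand here. A promoter of 1000 bp was run together with the gene, as given above. No list test was run for a promoter of 2000 bp, although 1036 genes had a peak within 2000 bp upstream. Read depth is unknown, so a gene outside the target table cannot be told from one below the detection limit.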

Other observations

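The comparison of microRNA genes with other genes and the tests of peak width and coverage on chromosome 1 and at AG were chosen after the values had been seen. The bound of the placement test for microRNA genes was set before its result. The genes named here were chosen after their values were seen. In the authors' deposited table, 31 of 326 microRNA genes (9.51%) were targets, against 6.62% of protein-coding genes (Fisher's exact test, two-sided p = 0.0436, not adjusted). No test per family was run. The families with more than 1 target were MIR165 and MIR166 (5 of 9 genes), MIR156 and MIR157 (5 of 14), MIR169 (4 of 14), and MIR159 and MIR319 (3 of 6). MIR165 and MIR166 genes, whose products repress the class III HD-ZIP genes PHB, PHV and REV, had scores of up to 587.12, at MIR166g, and the neighbours MIR166c and MIR166d share a peak of 199.53. MIR156 and MIR157 genes, whose products repress SPL genes, included MIR156e at 1558.62 and MIR156f at 1077.97. The latter peak lies 2000 to 3000 bp upstream. MIR172d, whose product represses AP2 and TOE3, scored 111.7, MIR167a, whose product represses ARF6, 358.33, and MIR319a, whose product represses TCP4, 58.19. MicroRNA genes lie between other genes, where most peaks are, and this was tested by random placement that kept each peak inside or outside genes. The 23 microRNA genes within 1000 bp of a peak were above the mean of 9.90 over 1000 placements and the 17.0 that bounds the middle 95% of them (permutation test, one-sided p = 0.001, the smallest they can give). Under these placements, the value argues against a position outside genes as the only cause. Neither the clustering of peaks nor their distribution along each chromosome was kept in the placements, so both stay open. Whether microRNA genes and the genes they repress are targets together more often than by chance was not tested.

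The broadest signal in the list was a run of 14 peaks on chromosome 1 from 9567556 to 9592023 (TAIR10), with gaps of at most 2000 bp. Peaks covered 70.2% of its 24468 bp, while no window of that length starting at another peak was covered by more than 26.4%. The nearest peaks outside it were 67712 and 104354 bp away. Its peaks were 1.99 times as wide as other peaks of equal score (permutation test, two-sided p = 2e-05, the smallest they can give). The run was picked for its span, so this width restates the choice, and separate point-like sites stay open. The annotation in the authors' deposited table describes AT1G27540, AT1G27550 and AT1G27580 as related F-box genes and AT1G27570 and AT1G27590 as related to each other, so the run holds related genes. A copy-number difference between the AG-GFP and control plants may account for it, but it stays open, because the coverage too follows from that choice and no read depth per library was used.

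The broad peak over AG could reflect extra AG sequence in plants that carry the AG-GFP transgene. Its width was 1.27 times the 4501 bp of the AP1 peak, the widest of the other 9 highest-scoring peaks, and the next widest was 748 bp. The AP1 peak is broad too, and AP1 is also the source of a transgene in these plants. Only 3 peaks in the list were wider than 4000 bp, those at AG and AP1 and the widest of the run on chromosome 1. The AP1-GR transgene is in both groups by the genotype labels, but its copy number in each group is not known here. The widths therefore neither single out added copies nor argue against them. Added copies cannot be told apart from broad occupancy of AG and AP1, since read depth per group was not analysed here.

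A further 144 peaks (10.1%) had none of the 1916 target genes with a known span within 3000 bp. The other genes of the 1958 have no span in the gene table, so they could not be placed. Their median score was 125, against 142 for the other peaks, and the highest, 1622.49, was on chromosome 1 from 11067660 to 11067931. Runs of 7 peaks on chromosome 3 from 12971244 to 12979907 and of 5 peaks on chromosome 5 from 11727238 to 11735488 were linked to none of the target genes with a known span.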
